A study of Mus musculus with 4 samples.

How the data were processed

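Single-cell RNA-seq was analysed for 4 libraries of mononuclear cells from skeletal muscle of mice aged 14 weeks. The sample labels gave a design of 2 genotypes (mdx5cv and mdx5cv/Ccr2-/-) by 2 muscles (quadriceps and diaphragm), with 1 library per group. How many animals went into each library, which part of Ccr2 is deleted and the genetic background of the knockout are not given in the sources used here. The deposited matrices hold raw UMI counts per gene and barcode, with no normalisation, made by the authors with Cell Ranger 6.1.2 per the file headers and on genome build mm10 per the submitters' processing notes. The annotation release, the treatment of intronic reads and the rule that separated cells from empty droplets are not given in the sources used here. The least covered barcode of each library held 500 to 502 UMIs.

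The counts covered 32285 genes and 33554 barcodes. Barcodes with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs were kept (31077). Doublets were scored with the Scrublet function of scanpy 1.11.5, which simulates pairs of cells. The highest-scoring barcodes of each library were removed at 0.8% per 1000 deposited barcodes. This removed 2508 barcodes, between 5.21% and 11.0% of those that passed in each library, and left 28569 cells. The share removed is an assumption about loading and not an estimate from these cells.

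The 4 libraries were clustered together with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9 in Python 3.11.15 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, no batch integration). Ccr2, sex-linked, mitochondrial, ribosomal protein, haemoglobin, dissociation stress and cell cycle genes took no part in clustering, nor did 248 further genes whose expression correlated with the cell cycle list over cells (r above 0.2). The plan did not name this correlation step. Values with only the fixed cell cycle list kept out are given among the alternatives below. Each of the 35 clusters was named from marker sets of 25 cell types, using markers detected in at least 10% of its cells and its 10 leading genes by fold among those detected in at least 25%. A name required at least 3 detected markers. A class named "X-like" rests on RNA markers alone. 4 clusters stayed unnamed. In clusters 22, 24 and 25 the leading genes over clusters of other classes held more markers of another class than of the best-scoring class. In cluster 27 the leading genes over all other cells held at least 3 more. Clusters 0 and 4, with an excess of 1 over all other cells, kept their FAP/fibroblast name. Cluster 24 was led by T-lineage genes such as Trdc, Cd3g, Cd3e and Cd3d, cluster 22 by endothelial genes such as Flt1 and Cldn5, and cluster 25 by fibroblast genes such as Dcn and Col3a1. The 4 unnamed clusters held 3.87%, 3.58%, 4.07% and 4.73% of cells in the order mdx5cv quadriceps, mdx5cv/Ccr2-/- quadriceps, mdx5cv diaphragm and mdx5cv/Ccr2-/- diaphragm. Values are listed in this order throughout where 4 are given. The macrophage-like class consisted of cluster 3, led by Ms4a7, Cx3cr1, Trem2 and the C1q genes, and cluster 8, led by F13a1, Cbr2, Folr2, Cd163 and Mrc1. The classical monocyte-like class was cluster 5, led by Chil3, Msr1, Ly6c2 and Spp1.

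With 1 library per group no difference has a replicate check, and no p-value, standard error or count of changed genes is given. A fit of genotype and muscle as additive factors, which would leave 1 residual degree of freedom, was not run. UMIs were summed per library and class and expressed as CPM, scaled to the total of that library and class. Ratios of CPM carry exact conditional binomial (Clopper-Pearson) 95% intervals, and shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, computed with scipy 1.17.1. These intervals cover counting error only and not the variation between animals, dissections or libraries. The intervals of CPM ratios take each UMI as independent, so they also leave out the variation between cells of a class. Shares of cells are compositional, so a lower share of a class does not give its absolute number. A count of 0 was taken to allow up to 3 counts. Class ratios were computed for classes with at least 100 cells in every library: macrophage-like, FAP/fibroblast-like (fibro-adipogenic progenitors and fibroblasts), endothelial-like, muscle stem cell-like and tenocyte-like cells. The ratios of Ccr2 are given in smaller classes as well. Genes counted as measured with a mean CPM of at least 20 and at least 50 UMIs over the 4 libraries. Measured genes were determined anew for each class, cluster and alternative, so medians of the same list can rest on different members. Log2 ratios used a pseudocount of 5 CPM.

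Before the data were examined, 25 gene lists, the marker sets, the rule for named genes and 18 processing alternatives were fixed. For each list the median log2 ratio of the measured members is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a p-value. The rule for named genes took genes whose ratio went the same way in both muscles with both intervals excluding 1, ranked by the smaller absolute log2 ratio, and left out mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed gene models and genes over 10 times higher in another class of the same library, whose counts could come from free RNA in the droplets. It named 12 genes each way in macrophage-like cells, 10 each way between muscles, 5 each way that moved oppositely in the 2 muscles, 8 each way in FAP/fibroblast-like cells and 3 each way in the other classes, with 2 to 4 members per list. Ccr2, Lyve1, Folr2, Timd4, Lgals3, Spp1, Gpnmb, Mki67, Ly6c2, Xist and Ddx3y were always to be given. Genes named outside this rule are said to be so. Some genes that the rule names are not reported here.

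Shares of cells with at least 1 UMI of a marker were compared after thinning each cell to 2000 UMIs and leaving out shallower cells. Where given, the share in a class that should lack the gene serves as the free-RNA background. As a test of free RNA, the rise of a gene in macrophage-like cells was divided by its level in all other cells of the library. For free RNA of 1 source class, which adds the same share of each of its genes, that share was bounded by the 5th percentile of level over source among genes of at least 100 CPM in the source. Gene positions were taken from the GENCODE mouse annotation of the GRCm38 (mm10) assembly, in which 32158 of the 32285 genes of the count tables had a position. TMM factors were computed with edgeR 4.0.16 in R 4.3.3, tables with pandas 2.3.3 and plots with matplotlib 3.10.9.

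The interval and list steps were tested on simulated counts drawn for macrophage-like cells with 200 genes changed by known folds. Of 5142 unchanged genes, 4.78% in the quadriceps and 5.54% in the diaphragm comparison had an interval that excluded 1. Of 65 genes changed 1.5-fold, 98.5% and 100% were recovered in the right direction. All 55 genes changed 2-fold and all 56 changed 4-fold were recovered in both comparisons. A list of 20 genes raised 1.5-fold lay at percentile 100, and 3.5% and 4.5% of lists of 15 unchanged genes lay outside the central 95%. These simulations hold counting error alone, so they do not show how repeated libraries of the same genotype would differ. Nor do they show how UMIs gathered in few cells would widen an interval.

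The alternatives changed the cell filter, the doublet share, the clustering, the denominator of shares, the scaling, the gene filter, the pseudocount, the correction for free RNA (5% of the profile of all cells subtracted, an assumed share) and the thinning depth, 1 at a time. A further 6 alternatives were added after the data had been seen. In macrophage-like cells TMM scaling moved the median log2 ratio over all measured genes by −0.12 in the quadriceps and −0.15 in the diaphragm genotype comparison, from 0.092 and 0.085. No other alternative moved a median over all genes by more than 0.1. List medians of macrophage-like cells smaller than these shifts are therefore given without a direction.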

Results

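Gene expression was measured in single mononuclear cells of the quadriceps and the diaphragm of mdx5cv mice, which lack dystrophin and model Duchenne muscular dystrophy, and of mdx5cv/Ccr2-/- mice, which in addition lack the chemokine receptor that brings classical monocytes from blood into tissue. The series asks what becomes of the resident macrophages of dystrophic muscle without Ccr2. There was 1 library per group. The mdx5cv quadriceps library held 56399477 UMIs over 5839 deposited barcodes and gave 4965 cells, and the mdx5cv/Ccr2-/- quadriceps library held 66330555 UMIs over 7492 barcodes and gave 6362 cells. The mdx5cv diaphragm library held 92189580 UMIs over 13175 barcodes and gave 11193 cells, and the mdx5cv/Ccr2-/- diaphragm library held 67356144 UMIs over 7048 barcodes and gave 6049 cells. Median UMIs per cell were 8003, 6627, 5885 and 8957. Xist, which is transcribed from the inactive X chromosome, had 3, 1, 3 and 1 UMIs, and the Y-linked gene Ddx3y stood at 59.2, 66.0, 71.1 and 77.6 CPM, the pattern of male cells in all 4 libraries.

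Transcripts of the targeted gene Ccr2 (ENSMUSG00000049103; chromosome 9, 124101950 to 124113557, plus strand, GRCm38) were 16.6-fold lower in the mdx5cv/Ccr2-/- quadriceps and 16.0-fold lower in the mdx5cv/Ccr2-/- diaphragm. Both folds are over all cells, so they also hold the lower share of monocyte-like cells given below. Over all cells the ratio was 0.0603 (95% interval 0.0563 to 0.0645) in the quadriceps, from 252 to 15.2 CPM, and 0.0624 (0.0570 to 0.0682) in the diaphragm, from 136 to 8.51 CPM, with 12709, 894, 10485 and 512 UMIs. In macrophage-like cells Ccr2 fell from 460 to 51.1 CPM and from 523 to 27.4 CPM. In classical monocyte-like cells the ratio was 0.0350 (0.0292 to 0.0416) in the quadriceps and 0.0850 (0.0485 to 0.138) in the diaphragm. Other markers of this class, given below, also differed between genotypes in the quadriceps. The ratio there may thus mix unlike cells with the loss of the transcript. Dendritic cells of the cDC2-like class kept more of the transcript, with 155 of 781 CPM in the quadriceps (ratio 0.199, 0.174 to 0.226) and 161 of 781 CPM in the diaphragm (0.207, 0.177 to 0.240), and 63.6% and 61.7% of these cells, unthinned at median depths of 11013.5 and 12381.5 UMIs, still had a Ccr2 UMI. FAP/fibroblast-like cells of the same libraries, which should lack Ccr2, had one in 0.150% and 0.138% of cells at median depths of 14634.5 and 10220 UMIs. Ratios were 0.193 and 0.274 in cDC1-like cells, 0.202 and 0.367 in NK-like cells, and 0.721 (0.374 to 1.42) and 0.166 (0.109 to 0.244) in T-like cells. The libraries thus carried the targeted gene at levels that match their labels, while the 3′ tags of a transcript with an internal deletion would still be counted, so the remaining UMIs do not measure working receptor.

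Macrophages and classical monocytes together, the phagocytes that clear dead fibres, made up a smaller share of cells without Ccr2 in both muscles. Their share was 30.1% (28.8 to 31.4) in the mdx5cv and 13.8% (13 to 14.7) in the mdx5cv/Ccr2-/- quadriceps, a ratio of 0.459 (0.422 to 0.499). In the diaphragm it was 16.8% (16.1 to 17.5) and 7.39% (6.74 to 8.08), a ratio of 0.441 (0.397 to 0.489). Classical monocyte-like cells alone went from 16.9% to 4.73% (0.281, 0.245 to 0.321) and from 3.43% to 0.678% (0.198, 0.140 to 0.273), which left 41 such cells in the mdx5cv/Ccr2-/- diaphragm. Macrophage-like cells went from 13.3% to 9.09% in the quadriceps (0.686, 0.612 to 0.768) and from 13.3% to 6.71% in the diaphragm (0.504, 0.450 to 0.562). As a share of the named immune classes, however, macrophage-like cells rose from 35.1% to 42.5% in the quadriceps and stood at 50.3% and 49.1% in the diaphragm. The boundary between the monocyte-like and the macrophage-like class moved with the clustering, and Ly6c2, a leading gene of the monocyte-like class, itself differed between genotypes. In the quadriceps the fall of monocyte-like cells was −12.1 points of all cells as given here, −4.33 points with a stricter cell filter and −4.15 points with each library clustered alone. Of the remaining monocyte-like cells there, 3.62% had Ly6c2 and 67.0% had Trem2 at equal depth, against 27.9% and 38.3% in mdx5cv.

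**Figure D1:**
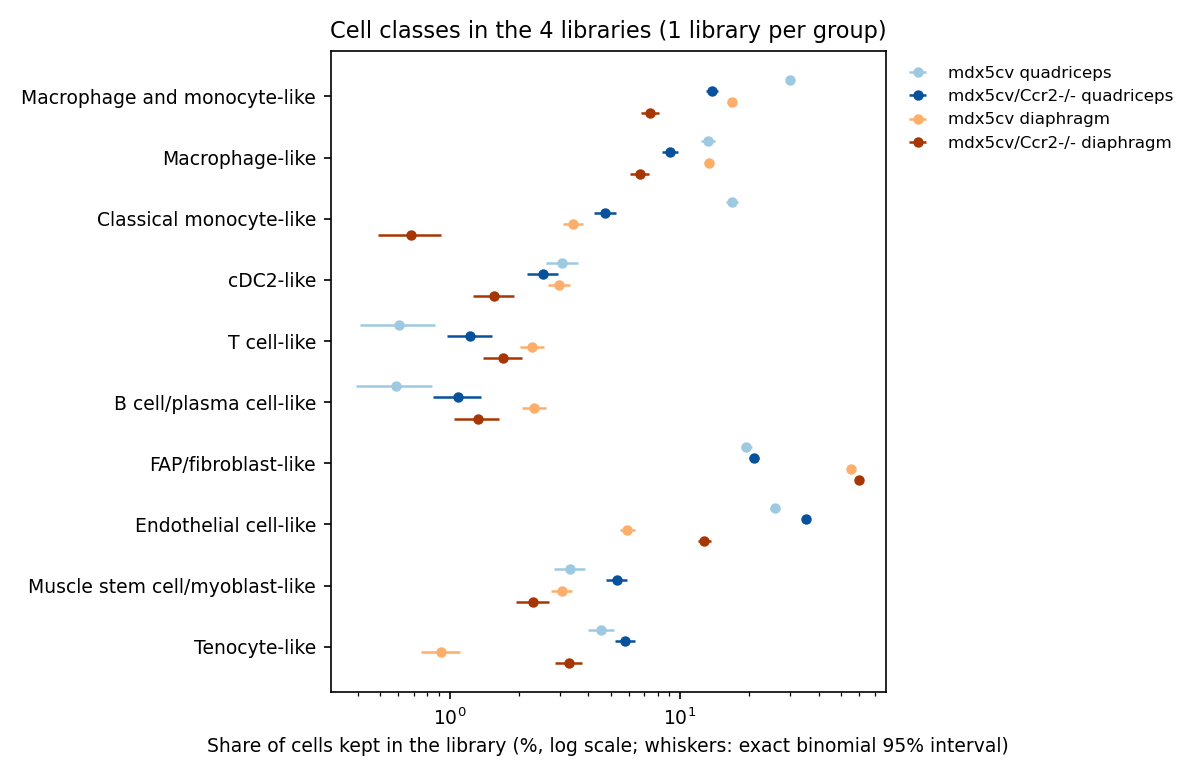
The horizontal axis shows the share of all cells in percent on a log scale for 10 cell classes, with 1 point per library and whiskers for exact binomial 95% intervals. Classical monocyte-like cells fell from 16.9% to 4.73% in the quadriceps and from 3.43% to 0.678% in the diaphragm without Ccr2, while FAP/fibroblast-like cells differed mainly between muscles.

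Within the macrophage-like class, cells with the profile of tissue-resident macrophages kept their share of all cells without Ccr2 while the other macrophages lost theirs. Cluster 8, led by F13a1, Cbr2, Folr2 and the scavenger receptors Cd163 and Mrc1, held 3.32% (2.84 to 3.86) of all cells in the mdx5cv and 2.97% (2.57 to 3.42) in the mdx5cv/Ccr2-/- quadriceps, and 3.97% (3.61 to 4.34) and 4.02% (3.54 to 4.54) in the diaphragm. Cluster 3, led by Ms4a7, the fractalkine receptor Cx3cr1, Trem2 and the C1q complement genes, went from 9.93% (9.11 to 10.8) to 6.11% (5.54 to 6.73) and from 9.36% (8.83 to 9.92) to 2.69% (2.30 to 3.13). As a part of the macrophage-like class, cluster 8 therefore rose from 25.1% to 32.7% in the quadriceps and from 29.8% to 59.9% in the diaphragm. These shares hold for 1 clustering, and an increase in the absolute number of resident macrophages cannot be read from them.

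The named immune classes together took a lower share without Ccr2, while B-like and T-like cells, as shares of all cells, went opposite ways in the 2 muscles. The named immune classes went from 37.8% to 21.4% in the quadriceps (0.566, 0.528 to 0.608) and from 26.5% to 13.7% in the diaphragm (0.516, 0.477 to 0.557). The antigen-presenting cDC2-like cells went from 3.08% to 2.55% and from 2.99% to 1.55%, and cDC1-like cells from 0.906% to 0.896% and from 1.13% to 0.661%. B-like cells had a ratio of 1.86 (1.19 to 2.97) in the quadriceps and 0.569 (0.437 to 0.734) in the diaphragm, and T-like cells 2.03 (1.32 to 3.20) and 0.744 (0.586 to 0.939). As shares of the named immune classes T-like cells were higher without Ccr2 in both muscles, at 1.6% and 5.73% in the quadriceps and at 8.63% and 12.5% in the diaphragm. B-like cells were higher in the quadriceps (1.55% and 5.07%). In the diaphragm their intervals overlapped (8.76%, 7.77 to 9.84, and 9.67%, 7.75 to 11.9). NK-like cells had ratios of 0.757 in both muscles (0.455 to 1.26 and 0.465 to 1.2). The unnamed cluster 24, led by T-lineage genes and not counted here as immune, held 0.322% and 0.597% of cells in the quadriceps and 1.22% and 1.5% in the diaphragm. In the diaphragm this cluster did not share the fall of the T-like class. That fall is therefore not read as one of T-lineage cells as a whole. Neutrophil-like cells were at 1.51% and 1.24% in the quadriceps and at 0.116% and 0.265% in the diaphragm, with a diaphragm ratio of 2.28 (1.03 to 5.15). Whether the genotype ratios of B-like and T-like cells differed between muscles was not tested.

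Among stromal cells, endothelial-like cells took a larger share without Ccr2, at 25.8% and 35.1% in the quadriceps (1.36, 1.27 to 1.46) and at 5.90% and 12.7% in the diaphragm (2.16, 1.95 to 2.40). The unnamed cluster 22, led by endothelial genes and not counted in these shares, went the other way. It held 2.76% and 1.95% of cells in the quadriceps and 0.661% and 0.413% in the diaphragm. Pericyte-like cells rose by ratios of 1.54 (1.28 to 1.86) and 1.71 (1.24 to 2.37), and tenocyte-like cells by 1.28 (1.08 to 1.52) and 3.58 (2.80 to 4.58). FAP/fibroblast-like cells, the matrix producers of muscle, had ratios of 1.08 in both muscles (0.990 to 1.17 and 1.04 to 1.13). Muscle stem cell-like cells rose from 3.32% to 5.33% in the quadriceps (1.60, 1.33 to 1.94) and fell from 3.06% to 2.30% in the diaphragm (0.750, 0.611 to 0.916), a difference between muscles that was not tested. Mesothelial-like cells, which cover the diaphragm, were 0.867% of the mdx5cv and 0.149% of the mdx5cv/Ccr2-/- diaphragm (0.172, 0.0762 to 0.340). None was found among 4965 and 6362 quadriceps cells, which allows shares of up to 0.0604% and 0.0472%. These shares do not give absolute numbers of cells.

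Between muscles, FAP/fibroblast-like cells made up 19.4% of the mdx5cv quadriceps and 55.1% of the mdx5cv diaphragm, a ratio of 2.84 (2.65 to 3.04), and 20.9% and 59.7% without Ccr2 (2.86, 2.68 to 3.04). Endothelial-like cells were scarcer in the diaphragm, with ratios of 0.228 in mdx5cv and 0.363 in mdx5cv/Ccr2-/-. Macrophages and monocytes together were also scarcer there (0.557 and 0.535), and the macrophage-like class alone had ratios of 1.01 and 0.739. Neutrophil-like cells had ratios of 0.0769 and 0.213. How readily each muscle came apart, which affects the share of every class, was not measured.

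Genes of tissue-resident macrophages stood higher in macrophage-like cells without Ccr2, and more so in the diaphragm. The haemoglobin scavenger receptor Cd163 (ENSMUSG00000008845) was 2.03-fold higher (1.74 to 2.37) in the quadriceps and 3.73-fold higher (3.42 to 4.08) in the diaphragm. The hyaluronan receptor Lyve1 was 1.80-fold (1.57 to 2.06) and 3.09-fold higher (2.76 to 3.47), at 41.9, 75.4, 49.1 and 152 CPM. The folate receptor Folr2 was 1.23-fold (1.16 to 1.30) and 2.34-fold higher (2.19 to 2.51), the growth factor gene Igf1 1.47-fold (1.39 to 1.56) and 1.63-fold (1.54 to 1.72), and the ficolin gene Fcna 2.35-fold (1.94 to 2.86) and 1.59-fold (1.28 to 1.97). Timd4, the receptor for phosphatidylserine on dead cells, had ratios of 4.78 (2.22 to 11.4) and 3.54 (2.58 to 4.90) at only 1.0, 4.78, 6.36 and 22.5 CPM. Of the 16 measured resident genes 12 were higher in both muscles and 0 lower in both. The list median was a log2 ratio of 0.27 (0.23 to 0.30) in the quadriceps and 0.83 (0.78 to 0.89) in the diaphragm, both at percentile 100 of random lists. The quadriceps value turned negative with stricter cell filters, finer clustering or libraries clustered alone. Within cluster 3 alone the medians were 0.0091 and 0.32 and within cluster 8 alone 0.16 and 0.049, but 7 leading genes of cluster 8 are members of the list, so this split does not separate a change of mix from a change within cells. The list had 12 measured members in cluster 3 and 19 in cluster 8, so these medians also cover different genes.

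The share of macrophage-like cells with a resident marker rose in the same way when each cell was thinned to the same depth. Lyve1 was found in 3.72% (2.39 to 5.48) of mdx5cv and 7.23% (5.24 to 9.68) of mdx5cv/Ccr2-/- quadriceps macrophage-like cells, and in 5.85% (4.70 to 7.20) and 15.9% (12.5 to 19.9) of those of the diaphragm. Cd163 was found in 3.87% and 7.94% in the quadriceps and in 8.36% and 25.1% in the diaphragm, Folr2 in 30.7%, 36.5%, 19.2% and 46.1%, and Timd4 in 0.464%, 1.59%, 1.05% and 5.82%. For Cd163, Folr2 and Timd4 no background share is given here. The Timd4 shares of the quadriceps rest on very few cells, so no rise of Timd4 there is claimed from them. FAP/fibroblast-like cells, which should lack Lyve1, showed it in 0.106%, 0.154%, 0.25% and 0.0841% of cells at the same depth. The thinned shares used 646, 567, 1435 and 395 macrophage-like cells, whose median depths before thinning were 13041.5, 10384, 6798 and 10146 UMIs, against 14195.5, 14835, 6647 and 10271.5 in FAP/fibroblast-like cells.

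**Figure D2:**
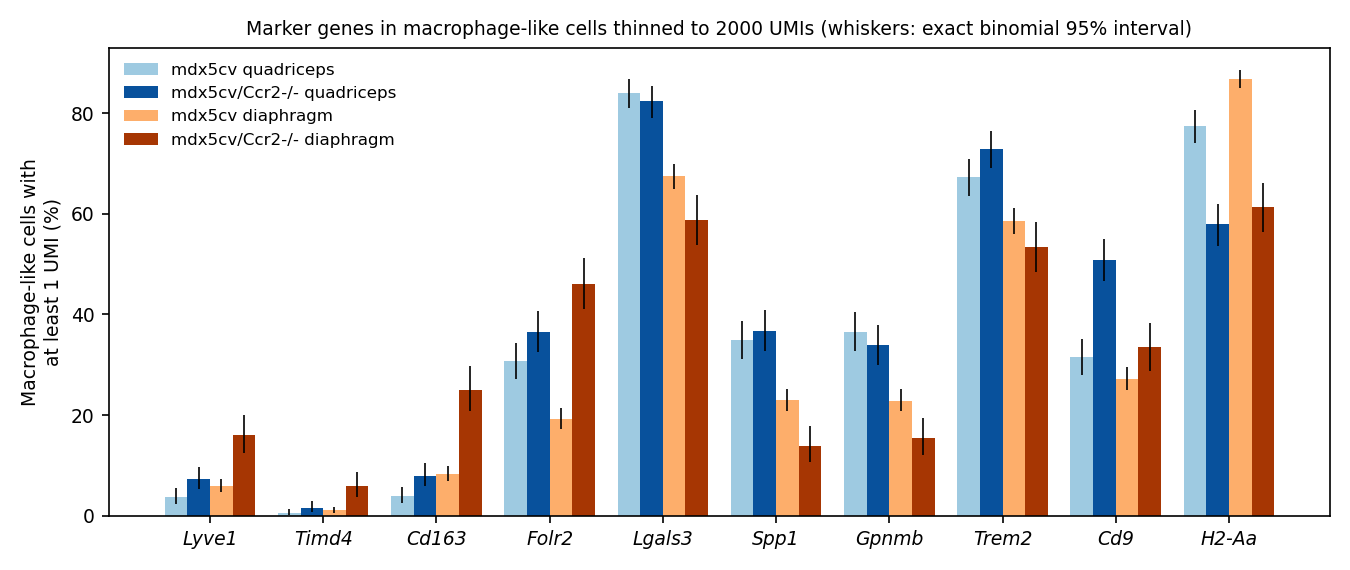
Bars show the percentage of macrophage-like cells of each library with at least 1 UMI of the gene after thinning to 2000 UMIs, and whiskers show exact binomial 95% intervals. The resident markers Lyve1, Cd163 and Folr2 were most frequent in the mdx5cv/Ccr2-/- diaphragm (15.9%, 25.1% and 46.1%), where Lgals3, Spp1 and Gpnmb were least frequent (58.7%, 13.9% and 15.4%).

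Genes of the lipid-associated, galectin-3-rich macrophages that surround damaged fibres did not move together with genotype within the macrophage-like class. Lgals3, which encodes galectin-3, was 1.11-fold higher (1.09 to 1.13) in the quadriceps and lower in the diaphragm at 0.829-fold (0.803 to 0.856), at 2385, 2641, 1383 and 1147 CPM. Spp1, which encodes osteopontin, had ratios of 0.932 (0.900 to 0.965) and 0.507 (0.476 to 0.540), and Gpnmb ratios of 1.0 (0.969 to 1.04) and 0.617 (0.577 to 0.658). The lipid receptor Trem2 stood at 1.06 and 0.771. The tetraspanin Cd9 was higher in both muscles, at 1.86-fold (1.77 to 1.95) and 1.39-fold (1.31 to 1.48), and Syngr1 lower in both, at 0.766 and 0.478. Cd36 (1.31 and 2.61) and Fabp4 (1.33 and 1.66) were higher, although both genes were far more abundant in other classes and could come from free RNA. Over 20 genes the median log2 ratio was 0.083 (percentile 67.8) in the quadriceps and −0.13 (percentile 5.4) in the diaphragm, with 8 higher in both muscles and 6 lower in both. The sign of these medians changed with scaling, doublet removal and the macrophage cluster used, so the list had no stable direction with genotype. The size of the medians also depends on the boundary with the monocyte-like class. At Leiden resolution 0.5, where no monocyte-like class was named, they were 0.38 and −0.29. Monocyte-like cells of the quadriceps, left out of this list, themselves differed in Trem2, Cd9 and Spp1, as given below.

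Lgals3 was found in 84.1%, 82.4%, 67.4% and 58.7% of macrophage-like cells at equal depth, against 4.30%, 5.90%, 2.00% and 0.816% of endothelial-like cells, and its order in the quadriceps, opposite to that of the CPM, is not read. Gpnmb was found in 36.5%, 33.9%, 22.9% and 15.4%, against 0.573%, 0.719%, 0.443% and 0.653%. In the diaphragm Spp1 was found in 23.0% and 13.9%, and in the quadriceps in 34.8% and 36.7%, where the order of the shares was opposite to that of the CPM and is not read. Cd9 rose from 31.4% to 50.8% and from 27.2% to 33.4%, with no class that lacks it to give a background. Endothelial-like cells had median depths of 5603, 5194.5, 3445 and 4682 UMIs before thinning.

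Antigen presentation genes of MHC class II were lower without Ccr2 in both muscles, for all 7 measured members. The class II beta chain gene H2-Ab1 had ratios of 0.766 (0.751 to 0.781) and 0.450 (0.440 to 0.459), the alpha chain gene H2-Aa 0.788 and 0.486, the invariant chain gene Cd74 0.814 and 0.543, and the peptide editor H2-DMa 0.779 and 0.506. The list median was −0.30 (−0.33 to −0.28) in the quadriceps and −1.01 (−1.04 to −0.93) in the diaphragm, at percentile 0 in both. The direction was the same within cluster 3 (−0.17 and −0.46) and within cluster 8 (−1.11 and −1.44). Cells with H2-Aa at equal depth fell from 77.4% to 57.8% and from 86.8% to 61.3%, while FAP/fibroblast-like cells showed it in 2.54%, 0.614%, 2.33% and 0.981%.

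Type I interferon response genes were lower without Ccr2 in macrophage-like cells of both muscles. The antiviral genes Ifit3 (ENSMUSG00000074896), at 0.222-fold (0.183 to 0.268) and 0.292-fold (0.239 to 0.353), and Ifit2, at 0.217-fold and 0.305-fold, were among the lowest. The ubiquitin-like modifier Isg15 had ratios of 0.265 and 0.338, and Irf7, the transcription factor that amplifies interferon production, ratios of 0.343 and 0.298. Of 13 measured genes 12 were lower in both muscles and 1 higher in both, and the list medians were −1.18 (−1.34 to −1.14) and −0.82 (−0.96 to −0.71), at percentile 0. The medians stayed negative within cluster 3 (−1.44 and −1.67) and within cluster 8 (−0.88 and −0.41), although Ifit2 was higher without Ccr2 in cluster 8 of the diaphragm. The list was also lower in FAP/fibroblast-like cells (−0.33 in both muscles), endothelial-like cells (−0.23 and −0.20) and muscle stem cell-like cells (−0.56 and −0.41), and stood at −0.075 and −0.088 in tenocyte-like cells.

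Single genes of other functions were also far below mdx5cv levels. Ms4a4c, a membrane protein gene of monocytes, had ratios of 0.258 (0.221 to 0.300) and 0.134 (0.109 to 0.165), and Ly6c2, the Ly6C gene of classical monocytes that was to be given whatever its value, 0.0328 (0.0119 to 0.0724) and 0.0262 (0.00845 to 0.0615), at 28.2, 0.925, 42.6 and 1.11 CPM. Apoc2, the cofactor of lipoprotein lipase, had ratios of 0.301 (0.258 to 0.349) and 0.247 (0.202 to 0.300), and complement factor B (Cfb) 0.28 and 0.256. Cyp4f18, which inactivates leukotriene B4, had ratios of 0.406 and 0.275, and the nucleic acid sensor Zbp1 0.419 and 0.415. The interferon-inducible genes Ifi209 (0.205 and 0.304) and Mndal (0.387 and 0.409) belong to a family of similar copies on chromosome 1 whose UMIs could be shared. The list of monocyte genes itself had a median of 0.091 (percentile 56.2) and −0.32 (percentile 0.4) over 6 members, with Plac8 at 0.0535 and 0.109 but over 10 times higher in another class.

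Among the genes named by the rule as higher without Ccr2 in macrophage-like cells of both muscles, the complement component C4b was 2.61-fold (2.22 to 3.06) and 3.18-fold (2.80 to 3.61) higher, with UMIs that could be shared with its near copy C4a. The lysosomal genes Ctsf (2.34 and 2.56) and Hgsnat (2.09 and 3.27), the aldo-keto reductase Akr1b8 (2.62 and 4.73) and the monoamine oxidase Maoa (2.63 and 3.31) were also higher, as were Cnrip1 (2.92 and 3.25), Cdr2 (2.85 and 2.55), Pmp22 (2.02 and 2.08) and Chp2 (2.09 and 2.48). The widest ratios were those of Sp140 (ENSMUSG00000070031; chromosome 1, 85600378 to 85645037), a chromatin reader of leukocytes, at 44.4-fold (23.1 to 98.1) and 50.7-fold (27.1 to 107), from 1.0 and 0.948 CPM to 44.4 and 48.1 CPM. Xlr was 5.45-fold (3.85 to 7.88) and 7.48-fold (5.81 to 9.71) higher. Sp140 and Xlr both belong to families with similar copies, so their counts are uncertain, and the strain background of the mice, which matters for a gene close to absent in 1 genotype, is not given in the sources used here.

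Iron handling and efferocytosis genes were higher as lists. The iron exporter ferroportin, Slc40a1, was 3.60-fold (2.87 to 4.55) and 1.58-fold (1.33 to 1.88) higher, the ferroxidase Cp 1.31-fold and 1.76-fold, and the haem transporter Slc48a1 1.2-fold and 1.35-fold. The iron and antioxidant list had medians of 0.27 (percentile 99.9) and 0.21 (percentile 98.1), with 9 of 12 genes higher in both muscles. Gas6, which bridges dead cells to their receptors, was 1.38-fold and 2.15-fold higher, while its receptor Axl was lower at 0.594 and 0.505. The complement and efferocytosis list had medians of 0.19 (percentile 98.8) and 0.36 (percentile 100), with 10 of 14 genes higher in both, and Mfge8 (2.22 and 2.72) was over 10 times higher in another class. Its members Gas6 and Stab1 also belong to the resident list.

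Inflammatory genes were mainly lower in the diaphragm. The cytokine gene Il1b had ratios of 0.751 (0.596 to 0.943) in the quadriceps and 0.366 (0.326 to 0.409) in the diaphragm, the neutrophil attractant Cxcl2 1.95 and 0.822, Tnf 1.22 and 1.17, and Ccl4, which was over 10 times higher in another class, 0.894 and 0.550. Over 9 genes the medians were 0.057 (percentile 32.8) and −0.28 (percentile 0.1). Among chemokines the interferon-induced Cxcl10 was lower (0.578 and 0.693), and Ccl24 (1.57 and 1.45) and the CCR2 ligand gene Ccl12 (1.39 and 1.93) were higher, while the receptor Cx3cr1 fell to 0.756 and 0.672. The list of 15 had medians of −0.045 and 0.34. The mannose receptor Mrc1, an alternative activation gene, was 1.21-fold and 1.72-fold higher, the lectin Clec10a lower (0.535 and 0.718) and Mgl2 split (0.799 and 1.43), with list medians of 0.079 (percentile 45.3) and 0.64 (percentile 100). Cd163 and Mrc1 of this list, and Ccl24 of the chemokine list, are also resident genes, so these lists are not independent of the resident list. Among profibrotic genes the growth factor genes Pdgfc (1.55, 1.32 to 1.83, and 2.48, 2.06 to 2.99) and Pdgfb (1.66 and 1.32) were higher in both muscles and Plau was split (0.738 and 1.58), with list medians of 0.30 (percentile 100) and −0.15 (percentile 1.2).

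**Figure D3:**
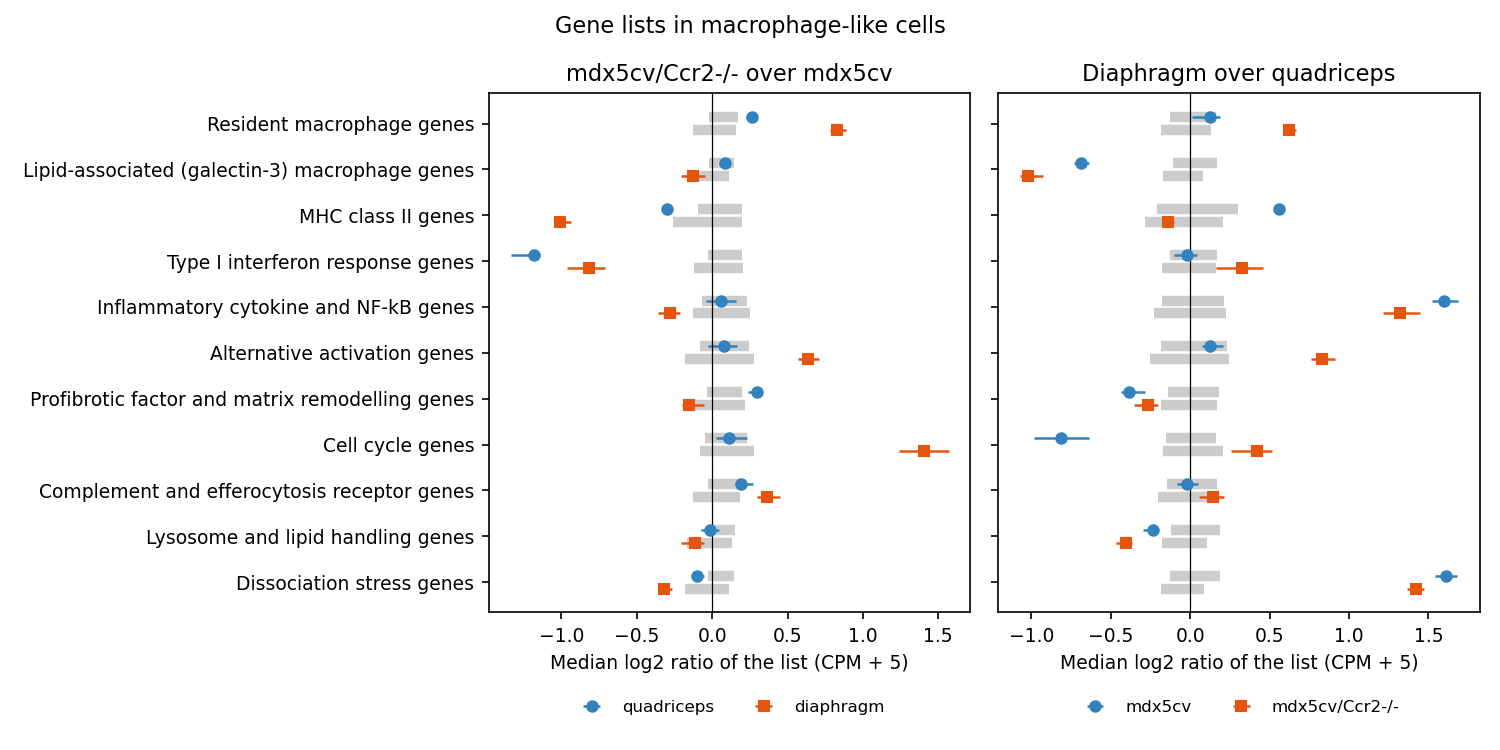
Points show the median log2 ratio of 11 gene lists in macrophage-like cells, mdx5cv/Ccr2-/- over mdx5cv in the left panel and diaphragm over quadriceps in the right panel, with counting intervals as whiskers and grey bands for the central 95% of random lists. Interferon genes lay at −1.18 and −0.82 and resident genes at 0.27 and 0.83 by genotype, and the stress genes at 1.61 and 1.42 by muscle.

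Proliferation genes were far higher in macrophage-like cells of the diaphragm without Ccr2. Mki67 had a ratio of 6.93 (5.76 to 8.37) there and 1.26 (1.09 to 1.45) in the quadriceps, at 45.3, 56.9, 14.7 and 102 CPM, the topoisomerase Top2a 6.1 and 1.30, the microtubule regulator Stmn1 2.98 (2.62 to 3.39) and 1.35 (1.23 to 1.48), and Pclaf 3.37 and 1.2. The list median was 1.41 (percentile 100) in the diaphragm and 0.11 (percentile 58) in the quadriceps, and in the diaphragm it was 1.39 in cluster 8 and 0.051 in cluster 3. These cluster medians rest on 15 measured genes in cluster 8 and 5 in cluster 3, so they are not directly comparable. At equal depth 1.95% and 4.56% of macrophage-like cells of the diaphragm had an Mki67 UMI, against 0.117% and 0.196% of FAP/fibroblast-like cells. Few cells held the gene and the ratio intervals take each UMI as independent, so they understate the uncertainty of Mki67. In the quadriceps 4.02% and 3.0% had one, an order opposite to that of the CPM that turned at other depths and is not read. Cycling genes were over 10 times higher in another class for 6 of the 10 members, Mki67 included, so free RNA of cycling cells of other classes was not excluded for these. The contrast with the quadriceps depends on the boundary of the macrophage-like class. In the quadriceps Mki67 was found in more monocyte-like cells without Ccr2, as given below. With both classes counted together, 11 of 11 measured cell cycle genes were higher in both muscles.

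Glycolysis genes had medians of 0.097 and 0.019, with Pgk1 at 1.25 and 1.34 and Eno1 at 1.32 and 0.881. Lysosome and lipid genes had medians of −0.013 and −0.11, although the cholesterol exporter Abcg1 (0.658 and 0.552), Pltp (0.763 and 0.774) and Apoe (0.826 and 0.671) were lower in both muscles. Adipogenic genes had medians of −0.15 and −0.088 with Cebpb at 0.721 and 0.683, fibroblast cytokine genes 0.049 and 0.89 with Tslp at 1.90 and 1.73, and sex-linked genes 0.18 and 0.32. Genes beside Ccr2 on chromosome 9 had medians of 0.055 (percentile 32.7) and 0.27 (percentile 98.2), with Lztfl1 at 1.38 and 1.48. Dissociation stress genes had medians of −0.10 and −0.32, with Junb at 0.866 and 0.791. Matrix genes (0.40 and −0.21, 6 of 6 members over 10 times higher in another class), fibroblast transcripts (0.29 and −0.052) and myofibre transcripts such as Acta1 (0.69 and −0.66) served as measures of free RNA. Of the haemoglobin genes 0 of 4 were measured in macrophage-like cells, where Hbb-bs stood at 29.1, 4.47, 3.22 and 0.891 CPM, and in endothelial-like cells their median was 3.03 in the quadriceps and 0.16 in the diaphragm. Of the neutrophil genes only Csf3r was measured, at 44.8, 20.4, 42.9 and 21.2 CPM.

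When macrophage-like and monocyte-like cells were counted as 1 class, monocyte genes were the lowest without Ccr2, with medians of −2.67 and −1.64 and 11 of 13 genes lower in both muscles. The chitinase-like Chil3 had ratios of 0.0788 and 0.0547 and Ly6c2 ratios of 0.0570 and 0.0259. Interferon genes (−1.46 and −0.76), MHC class II genes (−0.13 and −0.82) and inflammatory genes (−0.37 and −0.36) were lower, and cell cycle genes higher (1.36 and 1.62, 11 of 11 genes in both muscles), with Mki67 at 3.59 (3.26 to 3.95) and 7.50 (6.30 to 8.95). The resident list had medians of 0.095 (percentile 66.4) and 0.93 (percentile 100), with Lyve1 at 2.00 and 3.59 and Cd163 at 1.5 and 4.40. Lgals3 was 1.46-fold higher in the quadriceps and 0.605-fold in the diaphragm, with galectin-3 list medians of 0.38 and −0.29.

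Between muscles, macrophage-like cells of the diaphragm expressed less of the galectin-3 programme in both genotypes. Lgals3 in the diaphragm was 0.580-fold its quadriceps level in mdx5cv and 0.434-fold in mdx5cv/Ccr2-/-, Spp1 0.60-fold and 0.326-fold, and Gpnmb 0.510-fold (0.491 to 0.530) and 0.313-fold (0.294 to 0.334). The lipoprotein lipase gene Lpl had ratios of 0.442 (0.422 to 0.464) and 0.431 (0.402 to 0.462), the proton pump subunit Atp6v0d2 0.379 and 0.414, and the cathepsin Ctsl 0.468 and 0.488. The list medians were −0.69 (−0.73 to −0.64) with 19 of 20 genes lower and −1.02 (−1.07 to −0.93) with 18 of 20 lower, both at percentile 0. Also lower were Abcg1 (0.459 and 0.385), Qpct (0.274 and 0.444), Pld3 (0.506 and 0.460), Il18bp (0.504 and 0.345) and Pianp (0.490 and 0.391), the last of which was higher in the diaphragm within cluster 8 of mdx5cv. Lysosome genes had medians of −0.24 and −0.40 and profibrotic genes −0.38 and −0.27.

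Inflammatory and stress genes were higher in macrophage-like cells of the diaphragm in both genotypes. Il1b was 8.95-fold (7.79 to 10.3) and 4.36-fold (3.53 to 5.41) higher, Cxcl2 10.6-fold (9.56 to 11.7) and 4.45-fold (4.05 to 4.89), and the immunoglobulin-like receptor Lilra5 9.83-fold and 5.87-fold. The heat shock genes Hsph1 (6.05, 5.39 to 6.80, and 4.80, 4.19 to 5.50) and Hsp90aa1 (5.07 and 3.81) and the immediate early genes Ier3 (4.11 and 3.79), Dusp1 (4.02 and 3.28), Nr4a1 (3.98 and 3.57), Klf2 (3.44 and 3.26) and Phlda1 (3.37 and 3.49) were higher as well. The inflammatory list had medians of 1.60 with 9 of 9 genes higher and 1.32 with 8 of 9, and the dissociation stress list 1.61 (1.54 to 1.68) and 1.42 (1.36 to 1.47) with 16 of 16 in both. Handling of the muscles before capture acts on the same genes, so inflammation of the tissue and handling are not separated by these values.

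Resident genes differed between muscles mainly without Ccr2, where the diaphragm median was 0.62 above the quadriceps against 0.12 in mdx5cv. Lyve1 in the diaphragm was 2.01-fold its quadriceps level without Ccr2 and 1.17-fold in mdx5cv, and Folr2 1.07-fold and 0.563-fold. MHC class II genes were higher in the mdx5cv diaphragm (0.56) and stood at −0.14 without Ccr2. Alternative activation genes had medians of 0.13 in mdx5cv and 0.83 without Ccr2, cell cycle genes −0.81 and 0.42 with Mki67 at 0.324 and 1.79, chemokine genes 0.32 and 0.58, and interferon genes −0.017 and 0.33. Whether any muscle difference changed with genotype was not tested.

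FAP/fibroblast-like cells of the quadriceps expressed more extracellular matrix genes without Ccr2. Fibronectin (Fn1) was 1.81-fold (1.78 to 1.84) and 1.40-fold (1.38 to 1.42) higher, elastin (Eln) 1.30-fold and 1.22-fold, and the TGF-beta targets Ccn2 (1.36 and 1.38) and Pmepa1 (1.38 and 1.36) were higher as well, while Timp1 was lower (0.703 and 0.757). Of 20 matrix genes 14 were higher in both muscles and 3 lower in both, with medians of 0.48 (0.47 to 0.49, percentile 100) and 0.063 (0.052 to 0.072, percentile 98.1). The diaphragm median was close to that over all measured genes, 0.037, and lay between 0.018 and 0.18 under the alternatives. Also higher were Alad (2.58 and 2.26), the haem synthesis enzyme, Spon2 (1.59 and 1.85), Pxdc1 (1.56 and 1.48), Atp6v1g1 (1.60 and 1.41) and Pdzrn3 (1.51 and 1.37). The profibrotic list had medians of 0.21 and 0.086.

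The list of fibroblast cytokine genes fell in the quadriceps. The neutrophil chemokine Cxcl1 had ratios of 0.139 (0.123 to 0.156) and 0.434 (0.413 to 0.455), the hyaluronan synthase Has1 0.489 and 0.560, and the CCR2 ligand gene Ccl7 0.305 and 0.738, while complement C3 was lower in the quadriceps (0.408) and higher in the diaphragm (1.34). The fibroblast cytokine list had medians of −1.28 (−1.33 to −1.23) with 11 of 11 genes lower in the quadriceps and 0.053 with 6 of 11 higher in the diaphragm. Chemokine genes (−0.72 and −0.35) and inflammatory genes (−0.84 and −0.47, 4 of 4 lower in both) fell. Interferon-related genes were lower in both muscles, with Cxcl10 at 0.541 and 0.361, Ly6e at 0.787 and 0.775, and the guanylate-binding genes Gbp3 (0.555 and 0.537) and Gbp7 (0.608 and 0.622), Mndal (0.608 and 0.561) and Ifi203 (0.627 and 0.592). Wdfy1 (0.443 and 0.379) and the sterol enzyme Fdps (0.370 and 0.618) were also lower, as was Apod (0.513 and 0.776) in an adipogenic list with medians of −0.14 and −0.051.

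The FAP/fibroblast-like class differed in its mix of states between genotypes in both muscles. Cluster 7, led by Ptn, Cthrc1, Tnc, Lrrc15 and Adam12, genes of matrix-producing activated fibroblasts, made up 17.4% of the class in mdx5cv and 49.7% without Ccr2, and 3.96% and 3.41% in the diaphragm. Cluster 14, led by the cytokine genes Ccl7, Ptx3 and Ccl2 with Has1 and Timp1, made up 24.6% and 6.69% in the quadriceps and 4.80% and 2.99% in the diaphragm. In the diaphragm cluster 0 went from 34.4% to 24.3% and cluster 2 from 18.7% to 27.3%. Cluster 21, led by interferon genes, made up 0.830%, 0.902%, 3.76% and 3.30%. Between muscles, matrix genes were lower in the diaphragm (−0.27 in mdx5cv and −0.75 without Ccr2), as were cell cycle genes (−1.56 and −1.71), and stress genes were higher (1.68 and 1.40). The matrix and cytokine ratios of both muscles therefore mix a change of state shares with any change within a state.

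Muscle stem cell-like cells, as clustered here, expressed more cell cycle genes without Ccr2, with medians of 0.55 (18 of 21 genes higher) and 0.54 (19 of 21). The list was not rerun under the alternatives in this class, so its dependence on the clustering is not known. Myogenic commitment genes had a median of 0.20 (0.085 to 0.35) in the quadriceps and −1.13 (−1.22 to −1.04) in the diaphragm, and myofibre transcripts −0.26 and −2.84. Lower in both muscles were the fast troponin Tnnt3 (0.359, 0.261 to 0.491, and 0.116, 0.0831 to 0.157), the neuropeptide gene Gal (0.407 and 0.247) and Bex1 (0.347 and 0.122). Higher were Alad (3.39 and 2.94), the histone gene Hist1h2ab (3.66 and 2.45) and the cyclin Ccna2 (2.81 and 2.07), where the histone in the diaphragm and the cyclin in the quadriceps lost this direction when only the fixed cell cycle list was kept out of clustering. Hist1h2ab also has near copies, so its counts are uncertain.

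In endothelial-like cells Alad was 4.24-fold (3.23 to 5.65) and 4.09-fold (2.58 to 6.82) higher without Ccr2, and the glucocorticoid target Zbtb16 (1.71 and 2.53) and Skil (1.35 and 1.37) were higher too. The circadian gene Per1 (0.418 and 0.336), Wdfy1 (0.450 and 0.347) and Gbp3 (0.484 and 0.545) were lower. Cell cycle genes had medians of 0.47 and −0.12 and matrix genes 0.32 and −0.20. In tenocyte-like cells Pak3 (2.01 and 2.84), the transcription factor Snai2 (2.56 and 2.75) and the Wnt antagonist Sfrp4 (2.97 and 2.01) were higher, where Snai2 and Sfrp4 each changed direction in 1 muscle under other filters or clusterings. The sterol enzyme Idi1 (0.430 and 0.430), Wdfy1 (0.466 and 0.259) and the matrix protein Vit (0.455 and 0.430) were lower, although Vit in the diaphragm rested on 15 and 17 UMIs and kept its direction under only 10 of 13 alternatives. As a list, matrix genes had medians of 0.48 and 0.023.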

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

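A group of genes, gene lists and cell shares had values above mdx5cv in one muscle and below it in the other. In none of them was the difference between the muscles tested, and no explanation was tested for them.

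In macrophage-like cells Itgax, which encodes the integrin CD11c, had a ratio of mdx5cv/Ccr2-/- over mdx5cv of 1.41 in the quadriceps and 0.701 in the diaphragm. The motor protein gene Myo1e stood at 1.61 and 0.70, the receptor gene Slamf8 at 1.46 and 0.696, the transcriptional regulator Ifrd1 at 1.33 and 0.609, and the potassium channel gene Kcnn4 at 1.31 and 0.521. The opposite order was found for the ribonuclease genes Rnaset2a (0.408 and 1.78) and Rnaset2b (0.456 and 1.43), for Mthfsl (0.619 and 1.51) and for the tubulin genes Tuba1b (0.711 and 1.93) and Tuba1c (0.628 and 1.41). Rnaset2a and Rnaset2b are near-identical copies, as are the coding parts of Tuba1b and Tuba1c, so the division of UMIs within each pair is uncertain. Itgax, Ifrd1, Kcnn4 and Tuba1c each lost the direction given here under at least 1 other processing.

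Among gene lists in macrophage-like cells, profibrotic genes had medians of 0.30 and −0.15, chemokine genes −0.045 and 0.34, extracellular matrix genes 0.40 and −0.21, and myofibre transcripts 0.69 and −0.66. The chemokine median of the quadriceps is smaller than the shift between scalings and has no direction, so no opposite direction is claimed for that list. The myofibre list consists of genes over 10 times higher in other classes, so free RNA is not excluded for these values. Among shares of cells, the ratios were 1.86 and 0.569 for B-like cells, 1.60 and 0.750 for muscle stem cell-like cells and 2.03 and 0.744 for T-like cells. The opposite directions of B-like and T-like cells hold for shares of all cells only. As shares of the named immune classes T-like cells were higher without Ccr2 in both muscles (8.63% to 12.5% in the diaphragm). B-like cells were higher in the quadriceps, and in the diaphragm their intervals overlapped (8.76%, 7.77 to 9.84, and 9.67%, 7.75 to 11.9). The T-like class also leaves out the unnamed cluster 24, which held 1.22% and 1.5% of diaphragm cells. With 1 library per group these opposite directions have no replicate check, and differences between single dissections would look the same.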

How the results depend on the processing

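The 6 alternatives that used cluster 3 or cluster 8 alone, monocyte-like and macrophage-like cells summed, cells weighted to the mdx5cv mix of subclusters, FAP/fibroblast-like cells without clusters 0 and 4, or clustering with only the fixed cell cycle list kept out were chosen after the data were seen. Of 226 alternative values of the 18 results that answer a comparison, 111 stayed within counting error, 103 moved beyond it in the same direction and 12 reversed. Of 2696 alternative values of 202 other results, 2170 stayed within counting error, 508 moved and 18 reversed. A value counted as reversed only where the counting interval of the reported value left out no difference. Other changes of sign, such as those of Vit and of the Mki67 share given below, are not among the 18. The interferon list stayed negative under all 18 alternatives run for it in both muscles (−1.46 to −0.79 in the quadriceps, −1.67 to −0.41 in the diaphragm). The galectin-3 list stayed lower in the diaphragm than in the quadriceps under all 18 (−1.55 to −0.56 in mdx5cv, −1.52 to −0.69 without Ccr2), and the FAP/fibroblast matrix list stayed positive under all 16 (0.45 to 0.57 and 0.018 to 0.18). The resident list kept its direction under 15 of 19 in the quadriceps and 18 of 19 in the diaphragm, and the galectin-3 list by genotype under 16 and 14 of 18. No paired analysis was run, since the labels carry no replicate numbers, nor was a fit with muscle as a block. Vit in tenocyte-like cells of the diaphragm kept its direction under 10 of 13 alternatives (−1.12 to 0.22). The share of macrophage-like cells with Mki67 in the quadriceps changed by −1.03 points as reported and by 0.10 and 2.64 points at the other depths. Depth limits small classes, such as the 41 monocyte-like cells of the mdx5cv/Ccr2-/- diaphragm, and genes below about 20 CPM such as Timd4. Except where clusters or cells were picked or reweighted by construction, the cause was not tested for any value that follows.

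Shares are given in percentage points of cells and lists as median log2 ratios in macrophage-like cells, quadriceps before diaphragm for genotype and mdx5cv before mdx5cv/Ccr2-/- for muscle. The reported values were −4.17 and −6.62 points for macrophage-like cells, −12.1 and −2.75 points for monocyte-like cells, 0.27 and 0.83 for the resident list, 0.083 and −0.13 for the galectin-3 list, −1.18 and −0.82 for the interferon list, −0.69 and −1.02 for the galectin-3 list by muscle, and 0.48 and 0.063 for the matrix list in FAP/fibroblast-like cells.

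With the stricter cell filter macrophage-like cells changed by −12.1 and −9.04 points and monocyte-like cells by −4.33 and −0.504 points. The resident list reversed to −0.049 in the quadriceps and rose to 0.95 in the diaphragm, the galectin-3 list stood at 0.27 and −0.32, the interferon list at −1.42 in the quadriceps and the galectin-3 list by muscle at −0.82 and −1.51. Sfrp4 in tenocyte-like cells reversed to −0.25 in the quadriceps. Without a cell filter the quadriceps values were 0.20 for the resident, 0.15 for the galectin-3 and 0.46 for the matrix list, and Sfrp4 reversed to −0.64.

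With doublets kept the interferon list stood at −0.93 and −0.60 and the galectin-3 list by muscle at −0.56 and −0.78. With 2 times the doublet share removed, monocyte-like cells of the quadriceps changed by −13.7 points. The resident list then stood at 0.32 and 0.76, the galectin-3 list at 0.18 and, reversed, 0.015, the galectin-3 list by muscle at −0.63 in mdx5cv and the matrix list at 0.51 and 0.080.

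At Leiden resolution 0.5 no cluster was named classical monocyte, so that class has no value. Macrophage-like cells changed by −16.3 and −9.36 points, the resident list stood at 0.098 and 0.93, the galectin-3 list at 0.38 and −0.29, the interferon list at −1.46 in the quadriceps and the galectin-3 list by muscle at −1.52 without Ccr2. Ifrd1 reversed to −0.12 in the quadriceps, Snai2 in tenocyte-like cells to −0.010 in the diaphragm and Sfrp4 to −0.29 in the quadriceps. At resolution 2 macrophage-like cells of the quadriceps changed by −10.03 points and monocyte-like cells by −5.65 and −1.58 points. There the resident list reversed to −0.027 in the quadriceps, the galectin-3 list stood at 0.25 and −0.36, the interferon list at −1.09 and −0.55 and the galectin-3 list by muscle at −0.80 and −1.48. Ifrd1 reversed to −0.093 in the quadriceps and Tuba1c to −0.0042 in the diaphragm.

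With each library clustered alone, macrophage-like cells changed by −12.05 and −5.16 points and monocyte-like cells by −4.15 and −3.51 points. The resident list reversed to −0.037 in the quadriceps and stood at 0.66 in the diaphragm, the galectin-3 list stood at 0.25 and, reversed, 0.21, the interferon list at −1.42 in the quadriceps, the galectin-3 list by muscle at −1.55 and −1.48 and the matrix list at 0.57 and 0.18. Ifrd1 reversed to −0.026 in the quadriceps and Snai2 to −0.047 in the diaphragm. With only the fixed cell cycle list kept out of clustering, the resident list stood at 0.32 and 0.75, the galectin-3 list at 0.14 and the interferon list at −1.06 in the quadriceps, and the galectin-3 list by muscle at −0.63 in mdx5cv. Tuba1c reversed to −0.013 in the diaphragm, and in muscle stem cell-like cells Hist1h2ab reversed to −0.20 in the diaphragm and Ccna2 to −0.17 in the quadriceps.

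As shares of the named immune classes, macrophage-like cells reversed to 7.38 points in the quadriceps and changed by −1.19 points in the diaphragm, and monocyte-like cells by −22.5 and −7.98 points. Counted as 1 class, monocyte-like and macrophage-like cells changed by −16.3 and −9.37 points.

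With TMM scaling the resident list stood at 0.14 and 0.67, the galectin-3 list reversed to −0.046 in the quadriceps and stood at −0.26 in the diaphragm, the interferon list at −0.97 in the diaphragm, the galectin-3 list by muscle at −1.09 without Ccr2 and the matrix list at 0.45 and 0.018. Without mitochondrial and ribosomal protein genes the matrix list stood at 0.034 in the diaphragm. With each cell weighing the same, the resident list stood at 0.37 and 0.68, the galectin-3 list by muscle at −0.92 without Ccr2 and the matrix list at 0.54 in the quadriceps. Among genes of at least 100 CPM the diaphragm values were 0.90 for the resident and −0.25 for the galectin-3 list, the interferon list stood at −0.79 and −0.64 and the galectin-3 list by muscle at −0.56 in mdx5cv. With free RNA subtracted the galectin-3 list by muscle stood at −1.09 without Ccr2. The rise of Lyve1-positive cells in the diaphragm, 10.1 points as reported, was 4.96 points with cells thinned to 1000 UMIs and 16.5 points unthinned, as fewer or more UMIs per cell would give.

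In cluster 3 alone the resident list stood at 0.0091 and 0.32, the galectin-3 list at 0.23 and, reversed, 0.10, the interferon list at −1.44 and −1.67 and the galectin-3 list by muscle at −0.57 and −0.74, and Itgax reversed to 0.18 in the diaphragm. In cluster 8 alone the resident list stood at 0.16 and 0.049, the galectin-3 list reversed to −0.066 and 0.26, the interferon list stood at −0.88 and −0.41 and the galectin-3 list by muscle at −0.82 and −0.69. There Ifit2 reversed to 0.16 in the diaphragm, Pianp to 0.038 between the mdx5cv muscles, and Itgax to −1.05 and Kcnn4 to −0.36 in the quadriceps. With monocyte-like and macrophage-like cells summed, the resident list stood at 0.095 and 0.93, the galectin-3 list at 0.38 and −0.29, the interferon list at −1.46 in the quadriceps and the galectin-3 list by muscle at −1.51 without Ccr2, and Ifrd1 reversed to −0.12 in the quadriceps. With cells weighted to the mdx5cv mix of subclusters the resident list reversed to −0.045 and −0.17. In FAP/fibroblast-like cells without clusters 0 and 4 the matrix list stood at 0.55 and 0.018.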

Other observations

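The tests of the mix of macrophage subsets, of the handling of the muscles and of free RNA by level in other cells or by single gene, and the choice of the genes that differ in every class, were made only after the results they measure had been seen.

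Among monocyte-like cells of the quadriceps at equal depth, the lipid receptor Trem2 was found in 38.3% of the mdx5cv and 67.0% of the mdx5cv/Ccr2-/- cells, the tetraspanin Cd9 in 23.5% and 69.2%, Spp1 (osteopontin) in 40.7% and 67.8%, and the proliferation gene Mki67 in 2.00% (1.13 to 3.28) and 16.7% (12.5 to 21.6). Ly6c2, the classical monocyte marker, was found in 27.9% and 3.62%. In FAP/fibroblast-like cells of the same libraries Trem2 was found in 0.636% and 0.538%, Spp1 in 2.22% and 3.46%, Mki67 in 2.44% and 3.53%, and Ly6c2 in 0.212% and in 0 of 1302 cells, which allows up to 0.230%. The Mki67 shares of these FAP/fibroblast-like cells lay above the 0.117% of the mdx5cv diaphragm, so they are not taken as a background, and for Cd9 no class gives one. The monocyte-like shares rest on 749 and 276 cells with median depths before thinning of 10038 and 19184 UMIs, against 14195.5 and 14835 in FAP/fibroblast-like cells. In the mdx5cv/Ccr2-/- diaphragm only 23 monocyte-like cells were deep enough to be thinned, so no share is given there.

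Ifi202b (ENSMUSG00000026535; chromosome 1, 173962568 to 173982744), an interferon-inducible gene of the HIN-200 family that binds DNA, was close to absent in mdx5cv and present in both mdx5cv/Ccr2-/- libraries. Over all cells it had 1 UMI in the mdx5cv and 6149 in the mdx5cv/Ccr2-/- quadriceps, a ratio of 5269 (945 to 208145), and 7 and 9100 UMIs in the diaphragm, a ratio of 1662 (806 to 4135). In the mdx5cv/Ccr2-/- quadriceps and diaphragm it stood at 181 and 183 CPM in FAP/fibroblast-like cells, 117 and 154 in macrophage-like cells, 60.6 and 71.2 in tenocyte-like cells, 26.5 and 23.8 in endothelial-like cells and 8.52 and 13 in muscle stem cell-like cells. Neighbouring family members were lower in macrophage-like cells without Ccr2, with log2 ratios of −2.37 and −1.94 for Ifi213, −2.03 and −1.59 for Ifi209 and −1.16 and −0.63 for Ifi204, while the DNA sensor Aim2 stood at −0.020 and 0.27. In tenocyte-like cells family members were higher in the quadriceps, at 1.11 for Ifi204, 1.19 for Ifi211, 0.95 for Ifi203, 0.76 for Ifi207 and 0.71 for Mndal, against 0.26, −0.047, −0.18, −0.54 and −1.03 in the diaphragm. The family members are similar in sequence, so UMIs of 1 could be assigned to another, and the values of single members are uncertain.

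In macrophage-like cells of the diaphragm the resident genes, Cd163, Lyve1 and Folr2 among them, had a list median of 0.83 above mdx5cv. Free RNA of the other captured cells was argued against as the cause, because the rise was 32.8 times the whole level in all other cells (median over the list), where fibroblast transcripts reached 1.13% of theirs, while subtracting an assumed 5%, which gave 0.84, moved too little to decide. A different mix of macrophage subsets may account for it, since the median was −0.17 when mdx5cv/Ccr2-/- cells were weighted to the mdx5cv mix of subclusters made without the genes of the list. That weighting used the 6 of 13 subclusters with enough cells in both libraries, which held 87.7% of the mdx5cv/Ccr2-/- and 67.0% of the mdx5cv cells. Whether the mix changed because fewer monocyte-derived cells arrived, because resident cells multiplied or because the single dissections differed stays open and was not tested.

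Of 5350 genes measured in at least 3 of 5 large classes, 4 differed the same way by at least 0.5 in log2 in each class that measured them and in both muscles, with Ifi202b and the haem synthesis gene Alad higher and Wdfy1 and the guanylate-binding gene Gbp3 lower without Ccr2. Free RNA of 1 of these 5 classes was argued against for Alad, Wdfy1, Gbp3 and, in macrophage-like cells, Ifi202b. They stood at 0.532, 0.477, 0.249 and 0.646 of the highest class or more, where such RNA allows at most 0.20, 0.0086, 0.0054 and 0.010. It was not argued against for Ifi202b in tenocyte-like cells (0.335, at most 0.499). The median of 0.23 set beforehand does not decide because it took in classes that did not measure the genes. Only the 5 large classes were tried as the source, so free RNA of other classes was not tested. Strain variants carried with the knockout may be a cause, but 0 of the 4 genes had another within 2 Mb, and random sets of 4 genes had a mean of 0.0282. A pair of neighbouring genes would have lain above most random sets, so the test could have shown clustering. With so few genes the bound set beforehand was wrong, since a count of 0 is also what most random sets gave. The count of 0 therefore does not decide for or against strain variants. A weaker interferon response stays open for the genes that fell, since the highest interferon list median over the classes and muscles was −0.075, in tenocyte-like cells, while Ifi202b, itself interferon-inducible, rose. Strain variants, interferon and the loss of Ccr2 cannot be told apart here, because the strain background is not given in the sources used here and each genotype has 1 library per muscle, and a strain difference stays open and untested for Sp140 in macrophage-like cells as well.

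Dissociation stress genes, which include the immediate early gene Junb, were higher in the diaphragm in macrophage-like cells, with medians of 1.61 in mdx5cv and 1.42 without Ccr2. Free RNA of the other captured cells was argued against, since the rise was 1.13 times the whole level in all other cells in the genotype with the lower median, where fibroblast transcripts reached 1.13% of theirs, while subtracting an assumed 5%, with 1.43 as the lower median, moved too little to decide. Handling of the muscles before capture as a cause acting alike on all cells was argued against in mdx5cv, where muscle stem cell-like cells stood at −0.028 (−0.093 to 0.063) against 1.23 in endothelial-like cells, 1.68 in FAP/fibroblast-like cells and 0.98 in tenocyte-like cells. In mdx5cv/Ccr2-/- handling cannot be excluded, because every class was higher in the diaphragm and the lowest median was 0.48 (0.41 to 0.59), in tenocyte-like cells. A difference between the muscles themselves and an effect of handling that varies by cell class may both contribute and were not separated.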
